A study of Arabidopsis thaliana with 12 samples.

How the data were processed

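RNA levels were measured on an expression array of *Arabidopsis thaliana*, in 12 samples of total RNA from ecotype Landsberg. Per the labels, 6 samples came from dark-adapted wild type plants and 6 from the laf6 mutant, which had been dark adapted and then kept for 1 h in normal light. The laf6 mutant lacks atABC1, an ABC-type protein of the plastid that is also called SUFB. Genotype and light therefore changed together, and the only contrast the samples allow is of both at once. The labels do not say whether the numbered samples came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

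The deposited values are spot intensities on a linear scale, with 3439 probes per sample. How the authors corrected the background, scaled the arrays or set the limits of the scale is not given in the sources used here. The values were never negative. Between 13.0% and 19.3% of the probes of a sample were listed at exactly 0, and 1 to 5 probes per sample shared a ceiling at 100. The median intensity of a sample lay between 0.218 and 0.289 in wild type and between 0.161 and 0.170 in laf6. For arrays of this kind, the number of samples limits the precision.

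Probes were named through the platform's own annotation, which can be out of date. It gave 1 gene for 692 probes, several genes for 870 and none for 1877. Of the 692 probes, 690 matched a locus of the TAIR10.1 gene table, for 689 distinct loci. That table was used for names only. Probes with several genes were tested and counted but not named, and probes without a gene are called unnamed.

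Before the data were examined, it was decided that repeat readings would be averaged. The deviations of the samples from their group means were compared over 1387 probes with a mean intensity above 0.3. Samples of a group numbered 1 and 2, 3 and 4, or 5 and 6 had correlations from 0.10 to 0.57, and the other pairs of a group from -0.52 to -0.10. The standard deviation of the log2 differences between consecutive samples had a median of 0.32, against 0.55 for the other pairs. The 2 readings of each such pair were therefore averaged as intensities and counted as 1 replicate, which left 3 replicates per group. The pairs numbered 1 and 2 were the least close, with correlations of 0.19 in wild type and 0.10 in laf6. Their standard deviations, 0.50 and 0.54, lay within the 0.41 to 0.62 of the other pairs. By that measure they were not set apart as repeat readings, and they were averaged by their numbers all the same.

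Samples with the same number in the 2 groups also deviated together, with correlations from 0.33 to 0.65 over the same probes. For the averaged replicates these correlations were 0.62, 0.48 and 0.34, and over all probes 0.18, 0.098 and 0.16, so 1 of the 3 lay just under the limit of 0.1 there. The numbers were treated as pairing the samples, on the evidence of the values alone, since the labels do not say what a number marks. The planned test had no block, and values with the replicate number as a block are printed beside the counts of calls and the named genes.

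Values of 0 were set to the lowest positive value of the table, and all values were then taken to log2. Sample medians differed by up to 0.85 on the log2 scale, beyond the 0.2 set beforehand for leaving the table as deposited, so the replicates were quantile normalised. The groups were compared for each probe with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as laf6 in light minus wild type in darkness, and p-values were adjusted over all 3439 probes by the Benjamini-Hochberg method. A probe was called at an adjusted p under 0.05. Folds and log2 differences come from the normalised values, and intensities in the text are the deposited ones. No fold is given for a probe listed at 0 in every reading of a group, since the fitted value then depends on the lowest value of the table.

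The named genes follow a rule set beforehand. It takes the 12 largest positive and the 12 largest negative log2 differences among called probes with 1 gene whose groups did not overlap. Overlap was judged on the quantile normalised log2 values of the 12 samples before averaging. The rule also takes up to 3 members of each gene list with a called member, and SUFB. The 23 gene lists with 381 loci were also set beforehand. Lists with at least 3 measured loci were tested with limma's camera at a preset correlation of 0.01. A further 10 lists were drawn up after the names of the probes had been read and before any difference between the groups had been computed. The normalisation and the limma test were checked on simulated data in which 200 of the 3439 probes, outside the dimmest 25%, were changed. The simulated replicates had independent normal noise, with no readings to average, no pairing by number and no lower median in laf6. The check recovered 35% of the probes changed by 1 and 61% of those changed by 2 on the log2 scale. Of its 102 calls, 5.88% were false. These shares hold for that simpler setting only.

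Alternatives covered the normalisation, dim probes, eBayes with trend and robust settings, the replicate block, other ways of treating repeat readings, each replicate left out, a Welch test on all probes and other gene set tests. Added after seeing the data were a pseudocount at the 25th percentile of the table (0.0545) and the 12 samples without averaging. Both were also run with a block, which for the unaveraged samples was the sample number. A comparison without the samples numbered 1 and 2 was added then too.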

Results

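The data were 12 samples on one array design, 6 of dark-adapted wild type *Arabidopsis* and 6 of the laf6 mutant after 1 h of normal light, taken as 3 averaged replicates per group. The comparison addressed how gene expression in a mutant lacking the plastid protein atABC1 (SUFB), exposed briefly to light, differed from that of wild type plants kept in darkness. The mutated gene itself, SUFB (AT4G04770), was on none of the probes that the annotation names, so its level could not be used to check the labels. Every difference below is of genotype and light together.

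Among the named genes that rose in the illuminated mutant were PRK and AT2G04700. PRK (AT1G32060), the phosphoribulokinase of the Calvin cycle, rose 3.81-fold after normalisation. Its deposited intensity was 0.668 ± 0.186 in wild type and 2.08 ± 0.244 in laf6 (SD, n = 3 replicates each), a log2 difference of 1.67. AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, which passes electrons from ferredoxin to thioredoxins, rose 3.46-fold after normalisation. Its deposited intensity was 0.138 ± 0.0282 in wild type and 0.310 ± 0.0357 in laf6, a log2 difference of 1.19. AT4G31530, a protein with an NAD(P)-binding fold, fell from 48.0 ± 4.93 to 21.3 ± 2.95. AT5G63390, a member of the O-fucosyltransferase family, had an intensity of 0.180 ± 0.00616 in wild type and was listed at 0 in all 6 readings of laf6. These calls are from the planned fit, and with the replicate number as a block the adjusted p was 0.0948 for PRK, 0.0805 for AT2G04700, 0.0854 for AT4G31530 and 0.00835 for AT5G63390, whose value depends on the floor set for its zeros. With a pseudocount in place of the floor, chosen after seeing the data, and the same block, the adjusted p-values were 0.0442, 0.0404, 0.0420 and 0.0394. The lowest adjusted p of any probe in that setting was 0.0394, so all its calls lay close to the limit of 0.05.

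The log2 difference of PRK was 1.93 ± 0.30 (SE) with an adjusted p of 0.030 in limma, and that of AT2G04700 was 1.79 ± 0.20 with an adjusted p of 0.014. AT3G51510 had a log2 difference of 1.95 ± 0.21 after normalisation and 1.51 as deposited. Its deposited intensity was 0.274 ± 0.0744 in wild type and 0.773 ± 0.134 in laf6. AT5G53920 rose 3.75-fold and AT3G06870 rose 3.66-fold. AT5G19210, a DEAD-box RNA helicase, rose 3.19-fold with a log2 difference of 1.67 ± 0.14. AT1G32730 and AT1G69910, the latter a receptor-like protein kinase, rose 2.46-fold and 2.45-fold. AT3G14890, a DNA phosphatase of strand break repair, rose 2.33-fold after normalisation, from 0.157 ± 0.0510 to 0.229 ± 0.0135 as deposited. PRA1.B3 (AT5G05380), a prenylated Rab acceptor, rose 2.01-fold. The other 2 were AT2G46630, at 1.87-fold, and AT3G06570, at 1.79-fold, with 3.16 ± 0.603 in wild type and 5.43 ± 0.317 in laf6. With the replicate block, none of these 12 genes stayed past the threshold (adjusted p from 0.0674 to 0.123). With pseudocount and block together 11 did, all but PRA1.B3, each with an adjusted p between 0.0394 and 0.05. Without normalisation, AT3G14890 (log2 difference 0.60, adjusted p = 0.199), AT1G69910, PRA1.B3 and AT3G06570 were not called, and the differences of AT2G04700 and AT3G06870 were 1.19 and 1.27.

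Of the 12 named genes that fell, AT3G56130, a biotin/lipoyl attachment domain protein that acts on plastid acetyl-CoA carboxylase, fell by 1.04 (log2, normalised). Its deposited intensity was 0.270 ± 0.0241 in wild type and 0.0844 ± 0.0203 in laf6. AT2G32040, a plastid folate transporter, fell by 0.98 with an adjusted p of 0.04998, just within the limit. AT5G35100, a cyclophilin, fell by 1.13. AT5G52810 (SARD4), an enzyme of pipecolate synthesis in plant immunity, fell by 0.98 ± 0.11, from 3.08 ± 0.548 to 1.46 ± 0.143. The log2 difference of AT4G31530 was -1.55 ± 0.16 with an adjusted p of 0.0129. AT2G36480 fell by 1.17, and AT2G46300, of a hydroxyproline-rich glycoprotein family, fell by 1.03. AT5G49840, a ClpX-type ATPase, fell by 0.99, AT3G04650, an oxidoreductase, fell by 0.95, and AT3G43610, of a family of gamma-tubulin complex proteins, fell by 0.87. AT2G24810, a thaumatin family protein, had 0.0553 ± 0.0249 in wild type and was listed at 0 in all 6 readings of laf6. With the replicate block, AT5G63390 and AT2G24810, whose values depend on the floor, kept their calls and the other 10 did not (adjusted p from 0.0793 to 0.140). With pseudocount and block together 6 of the 12 were called, which were AT5G63390, AT4G31530, AT2G36480, AT2G46300, AT5G49840 and AT5G52810, while AT2G24810 was not (log2 difference -0.82, adjusted p = 0.0525). With replicates centred on their medians, AT4G31530 had a difference of -0.57 (adjusted p = 0.0662), and it, AT2G36480, AT2G46300, AT5G52810, AT2G32040, AT3G04650 and AT3G43610 were not called, while AT3G56130 had -1.70 without normalisation.

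**Figure D1:**
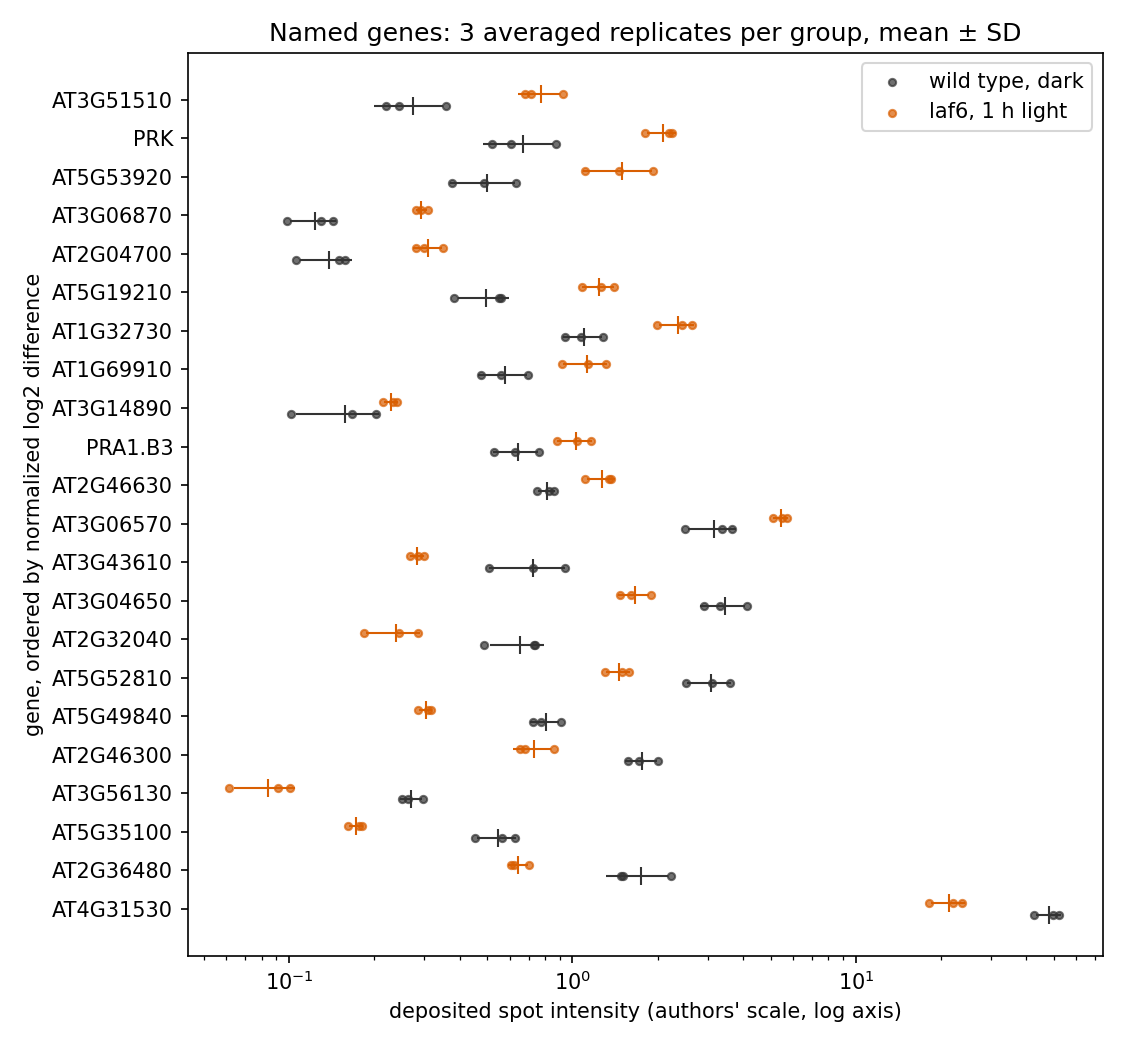
Deposited spot intensity (log axis) of the named genes that were not listed at 0 throughout a group, in wild type in darkness and laf6 after 1 h of light. Points are the 3 averaged replicates, bars show the mean ± SD, and the points of the groups do not overlap. The rule that chose these genes asked for no overlap in the normalised values of the 12 samples. As deposited, single readings of AT3G14890 overlapped (up to 0.208 in wild type and from 0.165 in laf6).

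Of the 381 loci on the lists set beforehand, 17 were measured by a probe of 1 gene, in 8 of the 23 lists. Of these 17, 1 rose, which was PRK, and none fell in limma. SBPASE, the other Calvin cycle gene measured, was listed at 0 in all 6 readings of wild type and in 5 of laf6, and was not called. Among genes of the photosynthetic membrane, PSAN of photosystem I had a log2 difference of 0.71 ± 0.17 (adjusted p = 0.0747) and LHB1B2, a chlorophyll-binding antenna protein of a family of near-identical copies, 0.57 ± 0.17 (adjusted p = 0.113). PSBY of photosystem II had 0.41 ± 0.15 (adjusted p = 0.183). As deposited these 3 had 0.70, 0.72 and 0.36. PSBW of photosystem II was at the ceiling in 1 reading, so its difference, -0.46 after normalisation (adjusted p = 0.187) and -0.12 as deposited, is not exact. Adjusted over the list alone, the 1 antenna gene, the 1 photosystem I gene, both photosystem II genes (PSBW with that limit), PRK and Z-ISO passed the threshold, where a list with 1 measured gene is left without adjustment.

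Z-ISO of carotenoid synthesis had a log2 difference of -0.73 ± 0.19 (adjusted p = 0.0917). In tetrapyrrole metabolism, CHLM and AT1G74470 (geranylgeranyl reductase) had 0.49 ± 0.41 and 0.23 ± 0.10, and in plastid fatty acid synthesis FATB, at 0 in 1 reading of wild type, and AT1G24360 had 1.60 ± 0.66 and -0.19 ± 0.15, none of them called or past the threshold when adjusted over the list alone. In the values as deposited CHLM had a difference of -0.05 and FATB 0.76. Plastid ribosomal proteins, with 6 of 38 loci measured, were the only list set beforehand that could be tested. They had 0 called members over all genes and 0 when adjusted over the list alone. Their median log2 difference was -0.14 and their mean -1.46, or a mean of -0.02 over the 5 other than AT1G29070, which was at 0 in all 6 readings of laf6, while camera gave the direction up with p = 0.572, or p = 0.593 with an estimated correlation. Listed loci outside these 17 had no probe of 1 gene and were not analysed here.

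Over the whole array, limma called 333 of 3439 probes, 188 higher and 145 lower in laf6 after light. With the replicate number as a block, which leaves 2 residual degrees of freedom, it called 4 higher and 9 lower. At an unadjusted p under 0.05 there were 423 higher and 467 lower. Probes with 1 gene made up 22 of the higher and 29 of the lower calls, unnamed probes 139 and 79, and probes with several genes 27 and 37. In every reading of one group, 4 of the higher and 18 of the lower calls were listed at 0. Among the other calls, 134 higher and 35 lower ones exceeded 2-fold.

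The median probe difference was -0.54 on the log2 scale in the values as deposited and -0.08 after quantile normalisation, so all normalised differences above are relative to that shift. It was larger for dim than for bright probes, with a median of -0.74 in class 5 and -0.25 in class 10, the brightest, of 10 about equal classes of probes by mean intensity, and 0 in class 1, the dimmest, where most values were 0 or close to it. The balance of the calls followed the scaling. It was 56.5% higher after quantile normalisation, 24.1% as deposited (114 higher, 360 lower) and 82.2% with replicates centred on their medians (208 higher, 45 lower). Of the 333 calls, 243 were also called as deposited, 109 higher and 134 lower, and 20 of the 24 named genes were.

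**Figure D2:**
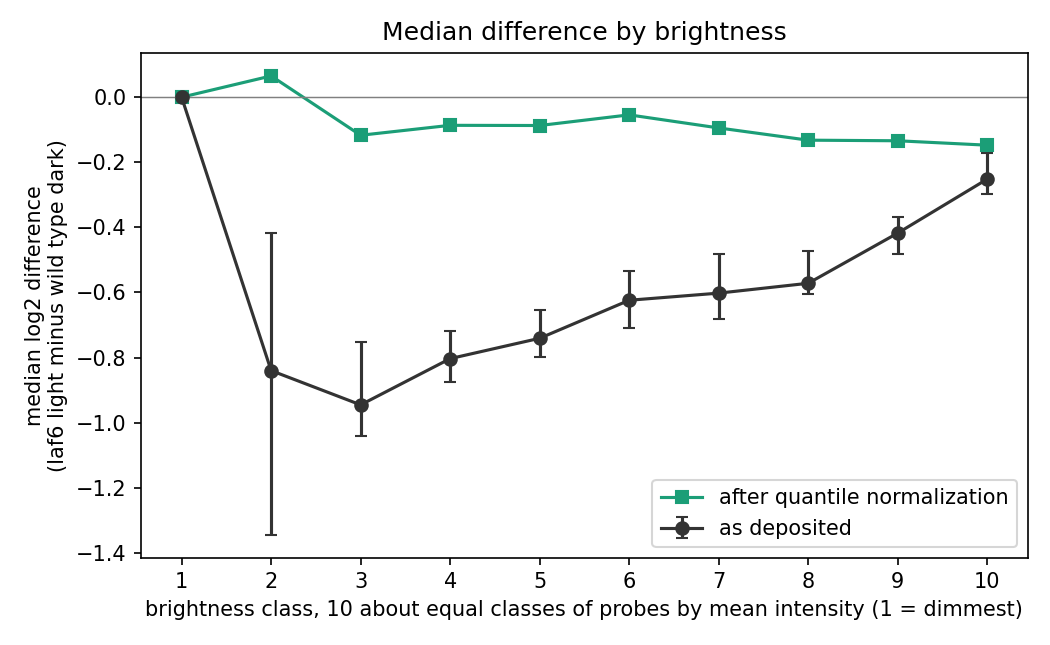
Median log2 difference (laf6 in light minus wild type in darkness) in 10 about equal classes of probes by mean intensity, from the dimmest to the brightest, as deposited with 95% bootstrap intervals over probes and after quantile normalisation. As deposited the median was -0.95 in class 3 and -0.25 in class 10.

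Leaving out any one replicate left between 93 and 194 calls, and a comparison of 3 replicates with 3 cannot reach an exact permutation p below 0.1. The 24 named genes kept the sign of their difference in every setting that tested them, which the rule of non-overlapping readings made likely beforehand. Of the 333 calls, 1 changed sign as deposited and 6 did with replicates centred on their medians.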

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

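The counts of calls moved with most settings. The named genes kept their sign in each that tested them, which the rule that chose them made likely beforehand. Against 188 probes higher and 145 lower, there were 114 and 360 without normalisation, and 208 and 45 with replicates centred on their medians. Without the dimmest 25% of probes there were 223 and 154. eBayes with trend and robust settings called 273 higher and 231 lower. With the replicate block, 4 were higher and 9 lower, with 2 residual degrees of freedom, while 877 probes had an unadjusted p under 0.05. Averaging numbers 1-4, 2-5 and 3-6 gave 342 and 347, and the 12 samples with the closest pair as a random block gave 305 and 344. The Welch test on log2 values of all probes called 16 and 14. Leaving out each replicate gave 59 to 113 higher and 32 to 81 lower, with fewer samples by construction. The totals were 155, 105 and 93 without wild type replicates 1, 2 and 3, and 148, 101 and 194 without laf6 replicates 1, 2 and 3. Chosen after seeing the data, the 12 samples unaveraged gave 353 and 421. With the 6 sample numbers as a block, in place of the averaged pairs, they gave 337 and 427 with 5 residual degrees of freedom. Both of these fits count the 2 readings of a pair as separate replicates. The 25th percentile pseudocount alone gave 260 and 209, and with the replicate block 174 and 121. The lowest adjusted p with pseudocount and block was 0.0394, so those calls all lay close to the limit of 0.05. Without the samples numbered 1 and 2, there were 21 and 31. Except where stated, the cause was not tested. Of the 24 named genes, 17 kept their call with medians centred and 17 with pseudocount and block together, 2 each with the block alone, the Welch test and without numbers 1 and 2, and 6 to 16 when a replicate was left out. PRK had log2 differences from 1.67 to 2.27 and adjusted p-values up to 0.164. Plastid ribosomal proteins, the only list set beforehand that could be tested, were not called in any setting run for them. Their camera p (limma) was 0.620 under the replicate block. The 10 further lists were run with the preset and the estimated correlation only. A pseudocount at the 10th percentile was planned but not run, since that percentile was 0, and SUFB had no value in any setting. Values near 0 cannot be ranked, and values at the ceiling are bounds.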

Other observations

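The tests of one scale factor, of one additive offset and of the probes listed at 0 were chosen after the results were seen, as were the spread over pairs given for the rescaling and the features named here. The 10 further gene lists had 4 called members, and limma's camera called none of the lists (adjusted p from 0.223 to 0.496, or 0.401 to 0.626 with an estimated correlation). SPPA (AT1G73990), a thylakoid protease, rose from near 0, with 5 of 6 wild type readings listed at 0, to 0.0303 ± 0.0138 in laf6, where 2 of 6 readings were at 0, so that the groups overlapped (adjusted p = 0.00691). GH9B11, a family 9 endoglucanase, fell by 1.02 ± 0.20 on the log2 scale (-1.68 as deposited), with normalised readings that overlapped. AT3G46950, an mTERF protein, fell by 0.60 ± 0.08. AT5G15280, a pentatricopeptide repeat protein, was listed at 0 in all 6 laf6 readings and in 2 of 6 of wild type. With the replicate block none of these 4 stayed past the threshold (adjusted p of 0.0834, 0.139, 0.0865 and 0.0782), and with the pseudocount and block together AT3G46950 did (0.0442). SRX, the sulfiredoxin that reactivates peroxiredoxins, was at 0 in 1 wild type reading and had a log2 difference of 2.98 ± 0.61 (1.88 as deposited) with an adjusted p of 0.0527. With the pseudocount and block together its difference was 1.31 (adjusted p = 0.0517 in limma).

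After quantile normalisation, median log2 differences of these lists were negative for histone H3 (-0.55 over 3 genes), endoglucanases (-0.93 over 4), floral and meristem regulators (-0.67 over 6), mTERF proteins (-0.36 over 6) and pentatricopeptide repeat proteins (-0.37 over 18, with 4 positive). As deposited these 5 medians were -1.10, -1.56, -1.17, -0.78 and -0.97. Without the genes at 0 throughout a group, the normalised median was -0.54 for floral and meristem regulators and -0.28 for pentatricopeptide repeat proteins. The mean of the pentatricopeptide list then went from -1.18 to 0.18. That mean still holds OTP85, with a log2 difference of 8.28 that depends on the floor. OTP85 was at 0 in 5 of 6 wild type and 3 of 6 laf6 readings (adjusted p = 0.138 in limma). The positive mean is therefore no sign of a rise of the list. The lowest camera p of these lists, 0.0317 before adjustment and 0.223 after it, was that of histone H3. Medians were positive for tetrapyrrole and siroheme enzymes (0.36 over 4 genes), photosystem, NDH and cytochrome subunits (0.10 over 15), fibrillins (0.44 over 5, with a mean of -1.25, or of 0.42 without AT2G46910, at 0 in all 6 laf6 readings), plastid chaperones and targeting (0.07 over 7, or -0.08 without the 1 gene at 0 throughout wild type) and redox enzymes (0.02 over 6). The last 4 were negative as deposited (-0.04, -0.25, -0.56 and -0.59), where the median of all probes was itself at -0.54, so their signs depended on the scaling. The photosystem list and the fibrillins lay above the median of all probes in both scalings (-0.54 as deposited, -0.08 normalised). Neither of these 2 lists was called.

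Some unnamed probes were also called. Probes 217 and 271 had log2 differences of -3.76 and -3.70 after normalisation. Their deposited intensities went from 5.17 ± 0.866 to 0.313 ± 0.0403 and from 4.33 ± 0.277 to 0.278 ± 0.0522. Probes 627 and 1629 rose by 3.85 and 3.51 after normalisation, with deposited intensities that went from 0.0543 ± 0.00888 to 0.493 ± 0.172 and from 0.0938 ± 0.0231 to 0.741 ± 0.0152. The log2 difference of probe 627 was 3.14 as deposited. With the replicate block none of these 4 stayed past the threshold (adjusted p from 0.0674 to 0.0865). With the pseudocount and block together all 4 did (adjusted p from 0.0394 to 0.0420). The log2 differences of probes 627 and 1629 were then 2.67 and 2.77, and those of 217 and 271 were -3.57 and -3.49. Another probe of these kinds had 35.3 ± 8.31 in wild type and was at the ceiling of 100 in all 6 laf6 readings. This gives only a lower bound there. Its adjusted p was 0.0275, and 0.111 with the replicate block.

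The median intensity was lower in laf6 after light than in wild type, with a median probe difference of -0.54 on the log2 scale and of -0.47, -0.67 and -0.29 in the replicate pairs. A single scale factor per replicate is argued against by a gap of 0.43 between class 10 and the middle classes of 10 brightness classes of probes (0.38, 0.59 and 0.35 in the pairs). One additive offset is argued against by a median intensity difference 4.79 times as large in class 8 as in class 3 (95% bootstrap interval over probes 4.02 to 5.77). That interval does not measure the spread between replicates, and the ratio was not computed for each pair. The scale factor and the offset were each tested alone, so both acting together stays open. A larger share of the total intensity in a few bright probes may be part of the lower median, if the arrays were scaled to a total. How they were scaled is not given, and the totals of the replicates ranged from 2950 to 3644, both in wild type. The brightest 1% held 46.5% to 47.7% of the total in laf6 and 38.0% to 40.0% in wild type. Rescaling to the total of the other probes left -0.33, with -0.21, -0.36 and -0.21 in the pairs, which decides neither way. A real change of many transcripts with genotype or light stays open and untested. Another technical difference between the groups cannot be told apart from such a change, since the labels do not say what a number marks.

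Of the probes above 0 in every reading of one group and at 0 in every reading of the other, all 11 were at 0 in laf6. Their wild type mean was below the median of all probes for 72.7%, with a highest value of 0.327, so low signal may account for many of them and cannot be told apart from loss of the transcripts, because most but not all of them were dim.

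The calls were not laid out in runs over the array as far as probe numbers show it. Neighbouring probe numbers had a rank correlation of 0.029 in their log2 differences (permutation p = 0.0917 from 10000 permutations), below the 0.05 set beforehand. Of the 10 splits of the 6 replicates into 3 and 3, only 1, the real one, gave as many as 188 probes higher, and only 1 as many as 145 lower, with 7 as the highest of the others in one direction. Splits into 3 and 3 are too few for a share under 0.05. The 3 other splits that also part all 3 replicate pairs called 3 to 5 probes in total.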
